A study of Arabidopsis thaliana with 26 samples.

How the data were processed

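Leaves of Arabidopsis thaliana were profiled on 26 single-colour arrays. The plants were the accession Col-0 and a line with a knockout of PIF5, a phytochrome-interacting transcription factor. Individual leaves were covered to exclude light while the rest of the rosette stayed in its light and dark cycle. Groups and replicate numbers came from the sample labels: 3 arrays for each genotype at 0, 1, 3 and 6 days of darkening and 2 arrays for pif5 at 12 days. The labels do not say that replicates came from separate plants, so p-values measure the spread between these samples, which may be technical. Scan or hybridisation batches were not given in the sources used here.

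The deposited table holds log2 values for 26676 probe sets, already summarised by the authors. The package oligo is named in the submitters' processing notes, with no version. The background correction, normalization and summarisation settings are not given in the sources used here. Per the labels, biotin-labelled cRNA was hybridised. Array medians lay between 4.20 and 4.33 and values between 2.24 and 13.50. The values are already on a common scale and no further scaling was applied in the main tests.

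Each probe set was tested in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit and eBayes). All 9 groups entered 1 fit, which left 17 residual degrees of freedom. Comparisons were each darkened group against day 0 of its genotype, pif5 against Col-0 at each shared day, pif5 day 12 against pif5 day 6 and Col-0 day 6, and the difference in response between genotypes as an interaction term. Adjusted p-values are Benjamini-Hochberg over all probe sets, with a threshold of 0.05. A change of 2-fold is 1 on the log2 scale. Comparisons of consecutive days, the share of one genotype's change seen in the other, the distance of arrays from straight lines between the Col-0 group means, and the check of row names described next were added after the data were examined. The number of arrays limits the precision of every value.

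No result is reported by gene name. Names entered only in the counts of list tests, in the choice of probe sets listed with 1 gene and in the check of the names themselves. The platform annotation given for the table lists 1 gene for 16179 probe sets, several genes for 588 and none for 9909. Symbols of 16067 probe sets could be updated through the TAIR10.1 gene table. Before naming genes, the names were set against the values. The 100 rows named for cytosolic ribosomal proteins, which are abundant and coexpressed in leaves, had a median level at percentile 55.2 of all rows. Random lists of 100 named rows spanned percentiles 39.7 to 59.0 in 95% of 10000 draws. The mean pairwise correlation of the ribosomal rows over arrays was 0.015, against -0.0034 to 0.024 for random lists. Rows named for the mitochondrial respiratory chain (47 rows, percentile 59.6) and for LCR small secreted peptides (22 rows, percentile 53.3), a family mostly silent in leaves, also lay within the range of random lists. A further 44 rows, named for neighbouring chromosome 2 loci, lay above the range of random lists but were picked after their values were seen. Their median percentile was 86.1 (random 34.7 to 64.0) and their mean pairwise correlation 0.25 (random -0.012 to 0.042). For the other lists the names were not borne out by the values, and rows are therefore cited by their identifier in the table. Whether an identifier belongs to the values beside it is open for the same reason.

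This changed the plan fixed before the data were examined. That plan named list members and, per comparison, the up to 8 largest rises and 8 largest falls among probe sets listed with 1 gene and with arrays that did not overlap between the groups. Only the first 2 rises and 2 falls of that rule for Col-0 at day 6 are given, by identifier. The level of PIF5, planned as a check of the genotype labels, was not analysed here, so the genotype labels are taken as given. Of 422 genes in 28 lists fixed beforehand, 76 had a listed row, and 12 lists had at least 3. Their tests are summarised only as counts. Cell type markers were not used here. A scaling by reference genes was not run, because it rests on the row names.

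The limma step was tested on simulated arrays with 200 changed probe sets among 26676. For Col-0 day 6 against day 0 it recovered 97% of changes of 1 and 100% of changes of 2 on the log2 scale, with 5 false calls. For the difference in response at day 6 it recovered 85% and 99%, with 11 false calls. The simulated noise was independent between rows and few rows changed, in a single group, unlike in the data. These rates may therefore not hold for the real comparisons. In simulated rows that shared a common factor the mean pairwise correlation was 0.58, and in other rows -0.0041. The factor was set to the size of each row's noise, so the former correlation followed from the setting. Alternatives were quantile normalization, centring arrays on their medians, leaving out probe sets whose highest group mean was below the 30th percentile of values, keeping only probe sets listed with 1 gene, moderated variances with a trend and robust estimation, array weights, a fit over the compared groups alone, a replicate block, a fit without pif5 day 12, and leaving out each array.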

Results

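The arrays measured transcript levels in leaves of Col-0 and pif5 plants before and during darkening of the single leaf. Correlations between replicate arrays of a group lay between 0.981 and 0.991. Over all 325 pairs of arrays, the smallest root mean square difference was 0.22 on the log2 scale within a group and 0.25 between groups, so no 2 arrays held identical values. By correlation with group means, each array left out of its own, 21 of the 26 arrays were nearest to their own group. In light, pif5 replicate 2 and Col-0 replicates 1 and 3 were nearest to the other genotype in light. Both pif5 day 12 arrays, whose own group then held 1 array, were nearest to pif5 day 6. The first 3 principal components held 55.7%, 14% and 10.8% of the variance. On the first, leaves in light lay at -89.0 ± 3.79 (SD, n = 3) in Col-0 and -88.3 ± 3.33 (SD, n = 3) in pif5. Darkened Col-0 leaves lay at 16.1 ± 2.53 at day 1, 52.6 ± 3.07 at day 3 and 65.8 ± 1.74 at day 6 (SD, n = 3 each). Darkened pif5 leaves lay at 10.2 ± 3.69 at day 1, 17.5 ± 7.72 at day 3 and 10.8 ± 3.94 at day 6 (SD, n = 3 each), and at 6.39 ± 10.81 at day 12 (SD, n = 2). On the second component, leaves in light lay at 18.0 ± 1.42 in Col-0 and 16.9 ± 0.71 in pif5 (SD, n = 3 each). Darkened Col-0 leaves lay at -11.2 ± 2.84, 21.1 ± 2.51 and 48.0 ± 1.00 at days 1, 3 and 6 (SD, n = 3 each), and pif5 at -19.7 ± 0.64, -24.4 ± 5.18 and -26.9 ± 6.85 (SD, n = 3 each) and at -32.7 ± 4.43 at day 12 (SD, n = 2). On the third component, leaves in light lay at -3.65 in Col-0 and 1.02 in pif5. Among darkened leaves the scores fell with the days in both genotypes, from 36.2 at day 1 to -15.7 at day 6 in Col-0 and from 31.4 to -30.5 in pif5.

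**Figure D1:**
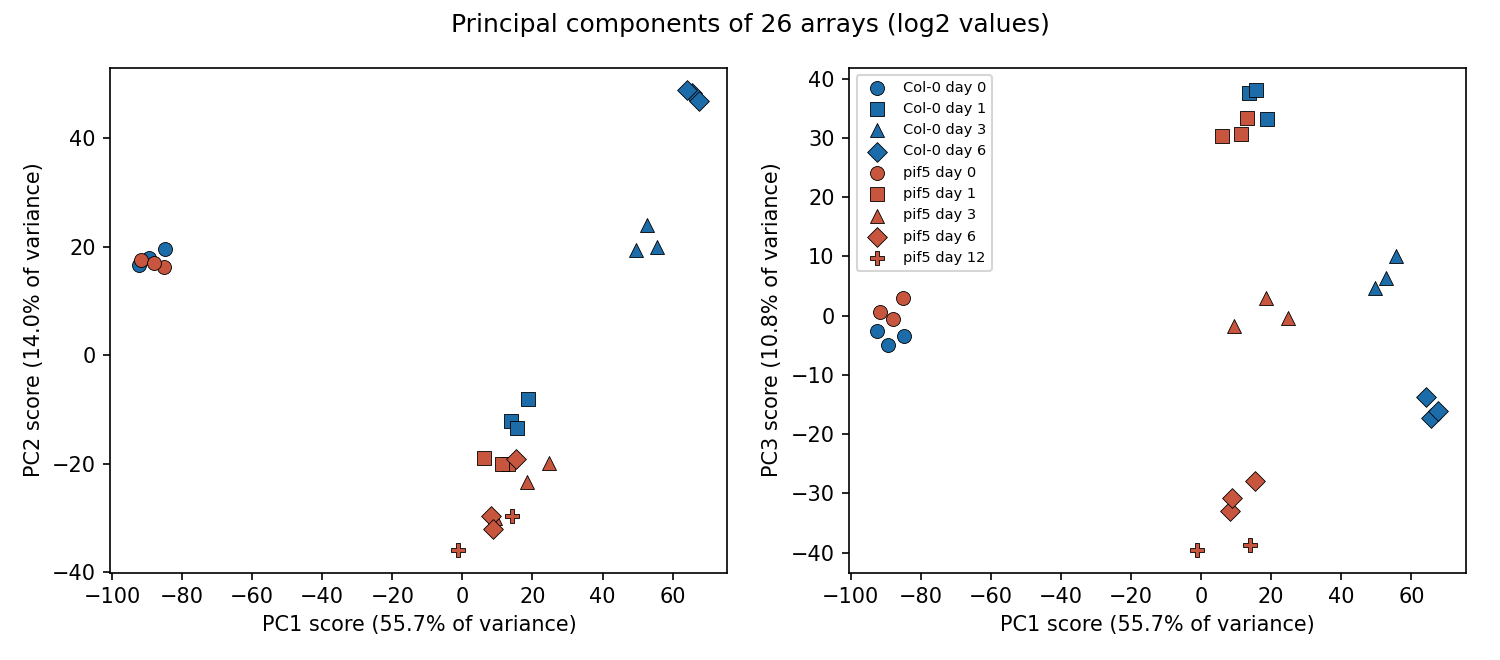
Scores of the 26 arrays on the first principal component against the second (left) and the third (right), with colour for genotype and shape for days of darkening. The 6 arrays of leaves in light overlap on the first and second components and not on the third, where all 3 Col-0 arrays lie below the pif5 arrays, and Col-0 arrays at days 3 and 6 stand apart from all pif5 arrays on the first component.

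In darkened Col-0 leaves 38.2% to 45.9% of the probe sets differed from leaves in light. The labels give a single group of leaves in light per genotype and none for the later days. Changes against light therefore do not separate darkening from leaf age or elapsed time. At day 1, 10196 of 26676 probe sets passed the threshold, 5180 higher and 5016 lower than in light. At day 3 there were 12126 (6244 higher, 5882 lower) and at day 6 there were 12237 (6203 higher, 6034 lower). Those that changed at least 2-fold numbered 3121, 4275 and 4756 at the 3 days, and at day 6 they were 2062 rises and 2694 falls. The median change over all probe sets was 0.01 on the log2 scale at day 6. The balance of rises and falls depended on the scaling: at day 6 it was 6647 to 5666 with quantile normalization and 7080 to 5469 with arrays centred on their medians. Between consecutive days, 4343 probe sets differed from day 1 to day 3 and 2798 from day 3 to day 6. Of the latter, 1505 were higher and 1293 lower at day 6, and 503 differed at least 2-fold, 392 upward and 111 downward. Without Col-0 day 3 replicate 2, 1839 probe sets differed between days 3 and 6.

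The largest rises and falls at day 6 were sought only among probe sets listed with 1 gene and with arrays that did not overlap between the groups. The rows with the largest rises among these lay below the array medians in light and at 10 or above on the log2 scale at day 6. Row 13533686 rose from 4.01 ± 0.20 in light to 10.09 ± 0.06 at day 1 and 10.81 ± 0.16 at day 6 (SD, n = 3 each), and the limma adjusted p at day 6 was 3.2e-17. Row 13492813 rose more slowly, from 3.71 ± 0.12 to 6.78 ± 0.26, 9.72 ± 0.18 and 10.04 ± 0.18 (SD, n = 3 each; limma adjusted p = 8.9e-12 at day 6). Row 13457018 fell from 11.39 ± 0.32 to 9.18 ± 0.23, 5.73 ± 0.34 and 4.83 ± 0.20 (SD, n = 3 each; limma adjusted p = 1.1e-19 at day 6). Row 13495603 did not pass at day 1, with a change of 0.10 and a limma adjusted p of 0.85. It then fell to 7.69 ± 0.24 at day 3 and 4.99 ± 0.22 at day 6 (SD, n = 3 each; limma adjusted p = 5.3e-16).

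In darkened pif5 leaves about as many probe sets differed from light at day 1 as later. There were 9348 past the threshold at day 1 (4446 higher, 4902 lower), 9436 at day 3 (4287 higher, 5149 lower), 9475 at day 6 (4066 higher, 5409 lower) and 8771 at day 12 (3644 higher, 5127 lower). The excess of falls depended on the scaling. Quantile normalization gave 4987 rises and 4488 falls at day 3, 5233 and 4465 at day 6 and 4856 and 4194 at day 12. Median centring gave 4744 and 4839 at day 3, 5249 and 4612 at day 6 and 5073 and 4237 at day 12. At least 2-fold changes numbered 2787, 3039, 2966 and 3116. From day 1 to day 3, 1924 probe sets differed, and 1263 in a fit over those 2 groups alone. From day 3 to day 6, 1661 differed, 146 of them at least 2-fold. The count of 1661 was 760 without pif5 day 6 replicate 1. Between day 6 and day 12, over a longer interval, 52 probe sets passed, 16 higher and 36 lower. That count rests on 2 arrays at day 12 and was 16 without pif5 day 12 replicate 2 and 100 without replicate 1. It was 0 in a limma fit over those 2 groups alone.

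**Figure D2:**
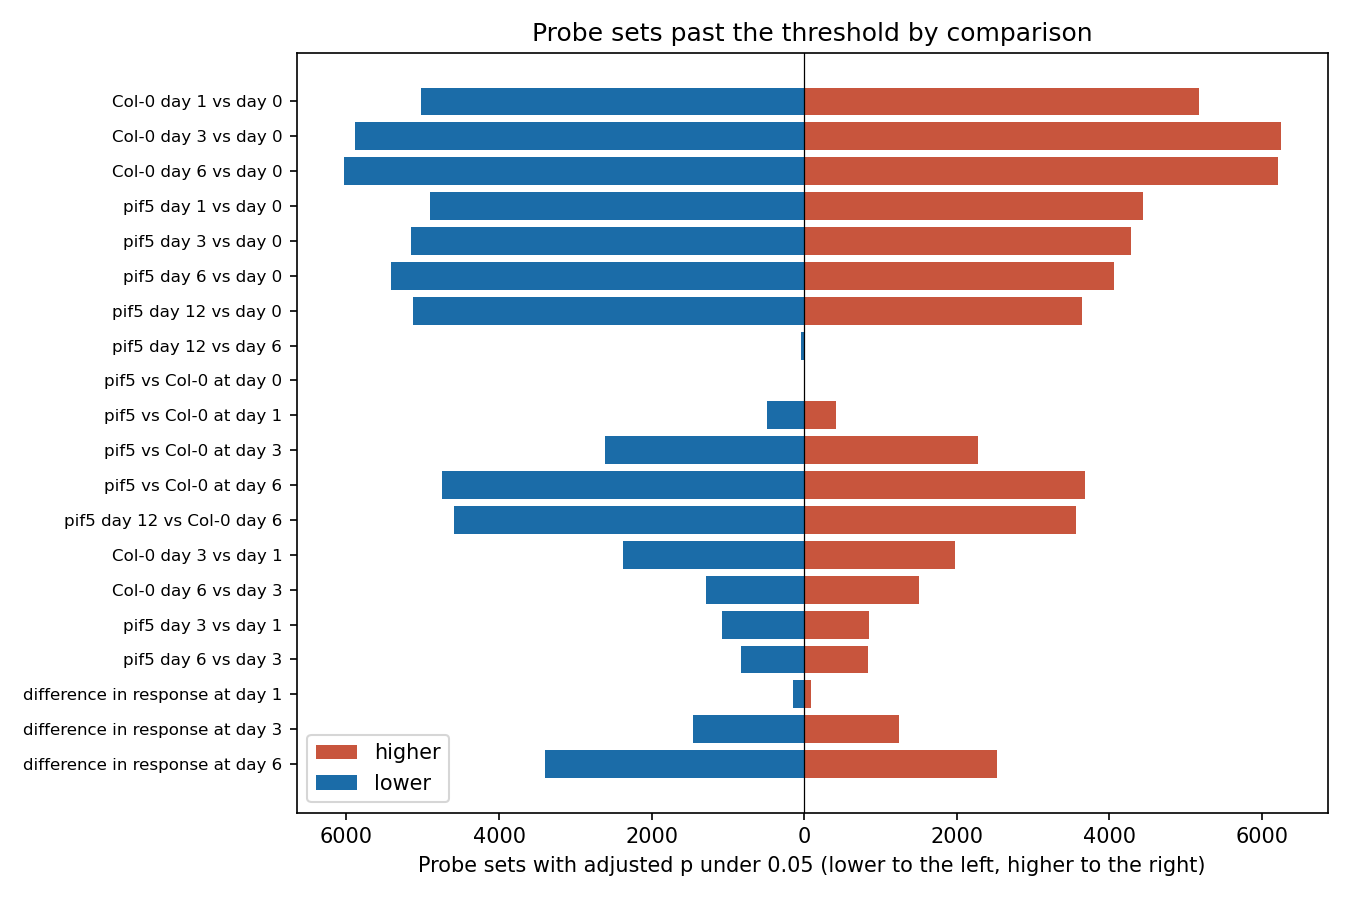
Number of probe sets past the adjusted p threshold in each comparison, with falls to the left and rises to the right of 0. For a difference in response, higher means a more positive change in pif5. The genotypes differed at 9 probe sets in light and at 8419 after 6 days of darkening.

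The genotypes were close in light and moved apart with the time in darkness. In light, 9 probe sets differed (3 higher and 6 lower in pif5), and the count was 30 without Col-0 day 0 replicate 1 and 2 in a fit over those 2 groups alone. At day 1, 908 differed (420 higher, 488 lower), with 555 without Col-0 day 1 replicate 2 and 576 in a fit over those 2 groups alone. At day 3, 4889 differed (2276 higher, 2613 lower), and at day 6, 8419 (3676 higher, 4743 lower), 2204 of them at least 2-fold. With quantile normalization the excess of lower calls was gone, at 2470 higher and 2406 lower at day 3 and 4198 and 4147 at day 6. With arrays centred on their medians it stayed, at 2089 higher and 2920 lower at day 3 and 3738 and 4653 at day 6. Leaves of pif5 at day 12 differed from Col-0 leaves at day 6 at 8156 probe sets. Averaged over days 0 to 6, 7318 probe sets differed between the genotypes, 266 of them at least 2-fold.

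The test of the difference in response itself gave 229 probe sets at day 1 (88 with a more positive change in pif5, 141 with a more negative one). It gave 2710 at day 3 (1248 and 1462) and 5923 at day 6 (2532 and 3391). With quantile normalization these were 1419 and 1290 at day 3 and 2940 and 2838 at day 6, and with median centring 1186 and 1551 at day 3 and 2657 and 3242 at day 6, so the excess of more negative changes depended on the scaling. A joint test over the 3 days gave 6105. The count at day 1 was 129 without Col-0 day 0 replicate 2 and 300 without replicate 1. At day 6 the 4 rows named above all passed. Row 13533686 had risen by 4.69 in pif5 against 6.80 in Col-0 on the log2 scale (limma adjusted p of the difference = 0.00029). Row 13492813 had risen by 1.59 against 6.33 (limma adjusted p = 7.8e-06), row 13457018 fell by 3.13 where in Col-0 it fell by 6.57 (limma adjusted p = 2.7e-09) and row 13495603 fell by 2.45 where in Col-0 it fell by 6.49 (limma adjusted p = 1.3e-07). They were chosen on Col-0, which favours a larger change there. At day 12 row 13492813 stood at 5.51 ± 2.44 in pif5 (SD, n = 2), so that its 2 arrays differed widely.

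**Figure D3:**
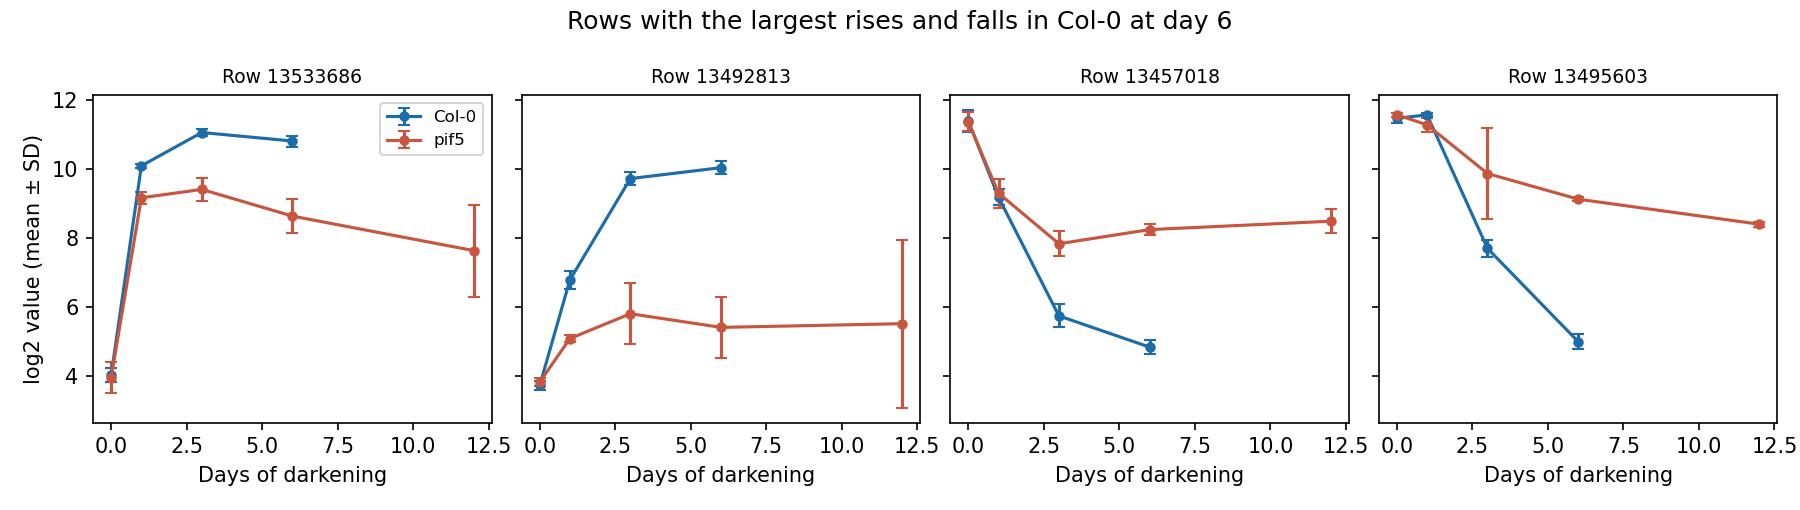
Mean log2 value with SD against days of darkening in Col-0 and pif5 for the 2 rows with the largest rises and the 2 with the largest falls in Col-0 at day 6 (3 arrays per point, 2 at day 12). At day 6 Col-0 lies at 10.81 and 10.04 for the rises and 4.83 and 4.99 for the falls, and pif5 lies between these and the level in light.

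Among probe sets that changed at least 2-fold in Col-0 at day 6, most changed less in pif5. At day 6, 6949 probe sets passed in both genotypes in the same direction and 461 in opposite directions, and independent lists would share 2169 in the same direction. Among the 2062 probe sets that rose at least 2-fold in Col-0, the median rise was 1.54 in Col-0 and 0.57 in pif5, and the median share of the Col-0 rise seen in pif5 was 36.3%. The rise was smaller in pif5 at 1958 of them, and the difference in response passed at 1546. Among the 2694 that fell, the median share was 69.6%, and the difference passed at 1251 with the smaller fall in pif5 and at 62 with the larger. At day 1 the shares were 85.7% for rises and 91.7% for falls, and at day 3 they were 63.6% and 77.6%. With quantile normalization the day 6 shares were 43.5% for rises and 65.0% for falls, and with median centring 40.6% and 67.6%. Choosing probe sets on Col-0 lowers these shares. When they were chosen on pif5 instead, the Col-0 change at day 6 was 106% of the pif5 rise and 110% of the pif5 fall. In that choice the rise was smaller in Col-0 at 432 of 921 probe sets. The difference passed at 256 rises with the smaller change in Col-0 and 274 with the larger, and at 291 and 547 falls.

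**Figure D4:**
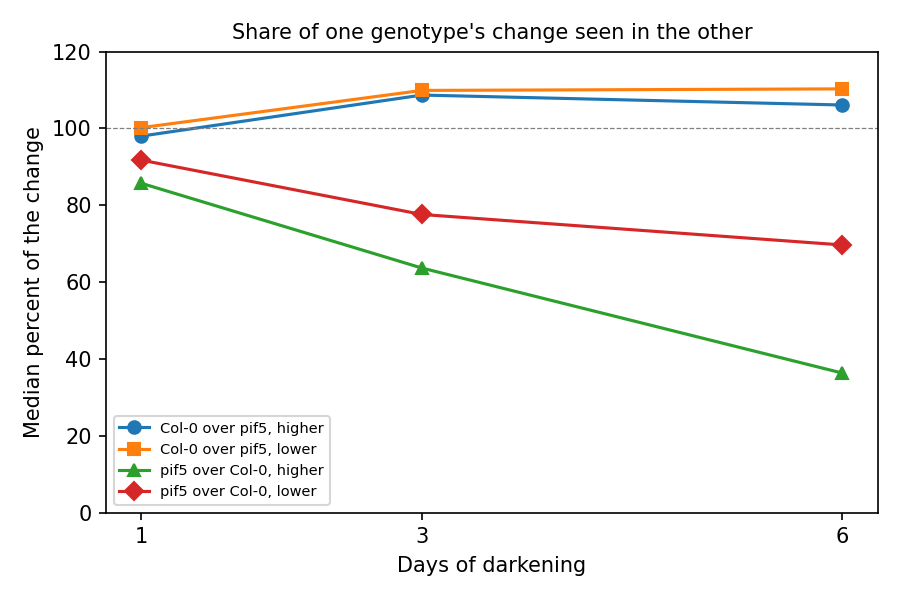
Median percent of the change in one genotype that was seen in the other, over probe sets that changed at least 2-fold in the first, against days of darkening. The share of Col-0 rises seen in pif5 goes from 85.7% at day 1 to 36.3% at day 6, and that of falls from 91.7% to 69.6%.

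Across probe sets, which are not independent replicates, the pif5 and Col-0 changes at day 1 had a Pearson correlation of 0.92. The pif5 change at day 3 correlated with the Col-0 change at day 1 with 0.87 and at day 3 with 0.88. The pif5 change at day 6 correlated with that of Col-0 at days 1, 3 and 6 with 0.76, 0.81 and 0.78, and the pif5 change at day 12 with 0.72, 0.75 and 0.73. Compared within each array, the correlation was highest with Col-0 day 1 in all 3 pif5 arrays at day 1, with Col-0 day 1 in 1 and Col-0 day 3 in 2 arrays at day 3, and with Col-0 day 3 in all 3 arrays at day 6 and both at day 12. At days 6 and 12 the lead of Col-0 day 3 over days 1 and 6 was 0.02 to 0.06. The nearest Col-0 day depended on the measure. Spearman correlations of the mean changes were highest with Col-0 day 3 for pif5 days 3 and 6 (0.750 and 0.648). For pif5 day 12 the highest was with Col-0 day 6 (0.586, against 0.584 with day 3). By root mean square difference, pif5 at days 3, 6 and 12 was nearest to Col-0 day 1 (0.37, 0.49 and 0.55). Against Col-0 day 3 these differences were 0.43, 0.52 and 0.59.

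Of the 12 gene lists that could be tested, none passed in any of 17 comparisons with camera, with a preset or an estimated correlation, after adjustment over the lists. The counts were 0 of 204 with either. With fry, which asks only whether the rows of a list moved one way on balance, 66 of 204 passed. Because the row names were not borne out, these counts describe rows and not pathways.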

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

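The tests of a constant difference between the genotypes' arrays, of a slower pace or a halt in pif5 and of the row names were chosen after the result was seen. The response to darkening differed between the genotypes at 229 probe sets at day 1, 2710 at day 3 and 5923 at day 6, and at 6105 in the joint test over these days, each by the interaction term of the limma fit. With genotype labels exchanged within days, 2 of 100 splits gave as many calls as the 5923 at day 6 (highest other 6140), and 3 of 100 as many as the 6105 of the joint test (highest other 7600). As many calls came in 7 of 100 splits for day 1 (highest other 461) and in 6 of 100 for day 3 (highest other 3233). The share is under 0.05 at day 6 and in the joint test and above it at days 1 and 3. Splits that exchange only arrays in light leave the darkened leaves in their groups, and these gave 150 to 461 calls at day 1, 2212 to 3233 at day 3 and 5440 to 6181 at day 6. Of these 20 splits, 13, 7 and 6 gave as many calls as the real one. The tallies thus depend on how many such splits were drawn, and they do not set day 3 apart from day 6. For the 7318 calls of the average over days, 1 of 100 splits, the real one, gave as many, and the highest other was 6843. Splits that exchange only arrays in light were not run for this average or for the joint test, so both tallies carry the same limit.

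The pattern weighed first is that darkened pif5 leaves changed less than Col-0 leaves by day 6. A constant difference between the genotypes' arrays would also appear in light, where 9 probe sets differed. Such a difference cancels in changes from each genotype's own day 0, so this count does not test the pattern. If array scaling were the cause, quantile normalization would remove most calls of the day 6 difference, and it left 5778. That count holds calls in both directions on values already on a common scale, so it does not decide the size of the change. The share of the Col-0 change seen in pif5 moved from 36.3% to 43.5% for rises and from 69.6% to 65.0% for falls. The size thus depended on the scaling, and the smaller change in pif5 stayed in probe sets chosen on Col-0. With 1 array left out, the lowest count of the day 6 difference was 5222, which again holds calls in both directions. The share of the Col-0 day 6 change seen in pif5, pooled over rises and falls, then stayed between 54.5% and 58.0%. A single misplaced array is argued against by these shares, for probe sets chosen on Col-0. If pif5 followed the Col-0 course at a slower pace or halted on it, its arrays at day 6 would lie near that course, drawn as straight lines between the Col-0 means at days 1, 3 and 6. Over the 4756 probe sets that changed at least 2-fold in Col-0 at day 6, the pif5 day 6 arrays lay 0.60 to 0.70 from it (root mean square, log2 scale). Col-0 day 3 arrays lay 0.43 to 0.46 from the course drawn without day 3. A course shared with Col-0 and merely slowed or halted is thus argued against at day 6, for these probe sets as a set. The pif5 day 3 arrays lay 0.45 to 0.55 from the course, which overlaps the range of the Col-0 day 3 arrays. A slowed or halted response to darkening, together with changes over elapsed time, would also leave the course and stays open. Single probe sets that lag or halt were not tested. Between days 3 and 6, 1661 probe sets also differed in pif5. A change of handling that affected only the darkened leaves of 1 genotype stays open, as does the genotype itself, which was not checked through PIF5.

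The pattern weighed next is that the gene names of the platform annotation do not go with the values. A constant offset between identifiers and values is argued against: over offsets of up to 3000 rows the median percentile of the ribosomal rows reached 69.0, and 100 random row sets reached 65.9 to 72.8. Signal from an overlapping gene on the other strand would raise rows whose gene overlaps another. Overlap was counted on either strand, so overlaps on the other strand were not tested apart. The 612 rows whose gene overlapped another by over 600 bases were higher by 0.20 on the log2 scale. The 95% bootstrap interval was -0.03 to 0.41, below the 1 set as its bound. Whether identifiers and values are without any relation stays open. A set of 44 rows named for neighbouring loci of 1 chromosome had a mean pairwise correlation of 0.25 and a median level at percentile 86.1, but it was picked after its values were seen, so this decides nothing. What separates names from values stays open, and no biological explanation was tested.

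Comparisons of 3 with 3 arrays have 10 splits, too few for a share under 0.05. In each comparison except pif5 against Col-0 in light, 1 split, the real one, gave the most calls. Every other split mixes both groups and so widens the spread within them. Where the groups differ widely, few calls in the other splits follow from this mixing, so they do not test chance. For Col-0 against light the real counts and highest other splits were 10196 and 1 at day 1, 12126 and 0 at day 3, and 12237 and 0 at day 6. For pif5 they were 9348 and 0, 9436 and 1, and 9475 and 0. Between genotypes they were 908 and 13 at day 1, 4889 and 0 at day 3, and 8419 and 0 at day 6. In light 2 of the 10 splits gave at least the real 9 calls, and the highest other gave 45. For consecutive days they were 4343 and 0 and 2798 and 1 in Col-0, and 1924 and 0 and 1661 and 4 in pif5.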

How the results depend on the processing

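Array weights, median centring, moderation with a trend, the filter on low probe sets and the fit without pif5 day 12 left every count of calls within 1.5 times its main value; median centring, the fit without day 12 and the comparisons of consecutive days were chosen after the data were examined. Deviations of same-numbered arrays from their group means had a mean correlation of 0.027 (-0.17 to 0.19), and those of other numbers -0.014. Centring on group means ties the second value to the first, so it is no separate comparison. Whether replicate numbers mark arrays handled together stays open. With the replicate block, 12346 probe sets passed in Col-0 at day 6, and no count moved by over 1.5 times. Among total counts, correlations and the share pooled over rises and falls, quantile normalization moved only 1 value beyond its bound. That was the correlation of the pif5 day 1 with the Col-0 day 6 change, from 0.77 to 0.76. The balance of rises and falls, and the shares of rises and of falls taken apart, did shift as given above.

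Keeping only probe sets listed with 1 gene, fewer by construction, lowered the counts about in proportion. For Col-0 at days 1, 3 and 6 they were 6043, 7262 and 7320, and for pif5 at days 1, 3, 6 and 12 they were 5559, 5586, 5635 and 5238. Day 12 against day 6 gave 32. The genotypes differed at 5, 500, 2871 and 4953 at days 0, 1, 3 and 6, at 4865 for pif5 day 12 against Col-0 day 6 and at 4276 on average. The difference in response gave 123, 1611 and 3531 at the 3 days and 3648 jointly. Consecutive days gave 2570 and 1627 in Col-0 and 1111 and 992 in pif5.

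Fitting only the groups compared, with fewer arrays for the spread, gave 0 for pif5 day 12 against day 6, 2 and 576 between genotypes at days 0 and 1, and 1263 for pif5 day 3 against day 1. Leaving out each array gave 16 to 100 for pif5 day 12 against day 6, where a lone array at day 12 is assumed to vary like the other groups. It gave 7 to 30 between genotypes in light, 555 to 847 at day 1, 129 to 300 for the difference in response at day 1, 1839 to 2371 for Col-0 day 6 against day 3 and 760 to 1711 for pif5 day 6 against day 3. The median share of the Col-0 day 6 change seen in pif5, pooled over rises and falls, was 56.4% and stayed between 54.5% and 58.0%. The separate shares of rises and of falls were not computed without single arrays. The list tests gave 66 calls with fry against 0 with camera; fry makes no comparison with other rows. Scaling by reference genes, the alternatives for named genes and PIF5, and list tests without single arrays were not run. The cause of other movements was not tested. Signal over background per array was not used here, so low rows have no stated detection limit.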
